A study of Caenorhabditis elegans with 4 samples.

How the data were processed

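The series holds 4 DNA samples of young adult Caenorhabditis elegans hermaphrodites carrying the fem-2(b245) mutation, grown at 20 °C. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an affinity-purified rabbit polyclonal antibody against MRE-11, a nuclease of the MRE11-RAD50 complex that processes DNA double-strand breaks. 2 samples are MRE-11 ChIP replicates and 2 are input DNA, the sheared chromatin before immunoprecipitation. Per the labels' protocols, frozen ground animals were crosslinked in EGS and then in EGS plus formaldehyde, and libraries were made from size-selected, PCR-amplified DNA.

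Reads were aligned with BWA to build ce10, per the submitters' processing notes. The authors deposited 3 peak lists, all on WormBase WS220 per the file headers: 1 list for each ChIP replicate, with the caller given as MACS, and 1 for the whole series, with the caller given as MACS v2. The deposited score of each peak is the peak caller's own value. No header names its unit. In the replicate lists no score lies below 50 and in the series-level list none lies below 1.30, and the scores of the list types were treated as different scales and compared only as ranks within a list. Whether the series-level list was called on pooled reads, which control was used and which settings separated the replicate calls is not given in the sources used here. The files hold intervals and scores without read counts, so the depth of each library is unknown, and no ChIP signal could be set against the input. The labels do not say whether the replicates came from separate cultures.

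Positions were used as deposited and are 1-based. Chromosome lengths were taken as the largest peak end in any of the 3 lists. The gene table at hand is for another assembly than WS220, so no peak was assigned to a gene. The planned tests of genomic features and gene lists and the planned values at mre-11, rad-50, spo-11, rad-51 and com-1 were therefore not made, and peaks are named by position.

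A peak was called shared where a replicate 1 and a replicate 2 peak overlapped by at least 1 bp, and the shared set was written as the replicate 2 intervals. Overlap was tested one-sided against 1000 random placements of 1 list on its own chromosomes with widths kept, which can give a p no smaller than 0.001. Peak numbers per chromosome were compared with length by exact two-sided binomial tests, and peak midpoints on the arms, defined as equal end segments that together make up 66.7% of each chromosome, with that share of the length. P-values were adjusted by the Benjamini-Hochberg method over 6 chromosomes and 4 lists for the first and over both chromosome classes and 4 lists for the second. Because neighbouring peaks are not independent, the same values were also tested by permuting 100 kb windows with 100000 resamples, a test chosen after seeing the data, whose smallest p is 1e-05. Clusters that span several adjacent windows, such as III between 1.0 and 2.5 Mb, are broken up by it, so its p-values can still be too small. Replicates were compared by Fisher's exact test. These comparisons, the groups by score, the correlations apart for X and autosomes, the X share of the top peaks and the comparison of named peaks on X and autosomes were also chosen after seeing the data. Intervals are 95% exact (Clopper-Pearson) binomial intervals and cover counting error only. Every p over peaks describes these lists and not the spread between samples, and no test across the 2 replicates was made.

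The rule for named peaks, set before the data were examined, took the shared peaks with the 20 highest mean percentile ranks of the score over both replicates. The 20th place was tied, because 37 replicate 1 peaks and 70 replicate 2 peaks carry the score 3100 exactly, so 35 peaks were named. The alternatives were the upper 50% of each list by score, 2 other overlap rules, circular shifts, covered bases in place of peak numbers, shorter arms, each replicate alone and another pairing of scores. Covered bases were tested by permuted windows and not by the binomial test. The overlap test was checked on simulated lists: 1 of 20 pairs of unrelated lists gave p under 0.05, and 400 of 400 planted overlaps were recovered. In the chromosome comparison a simulated X density of 0.5 relative to chromosome I was recovered as 0.504 from 3941 peaks, and 0 of 20 even lists gave p under 0.05 in the window test. All simulated lists were placed without clusters, so these checks do not show how the tests behave with clustered peaks. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.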

Results

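MRE-11 occupancy was profiled by ChIP-seq in fem-2(b245) young adult hermaphrodites, which contain a germline. fem-2 encodes a phosphatase of the sex-determination pathway that promotes male development and sperm formation. The design asks where in the genome MRE-11 is found, with 2 ChIP replicates and 2 input samples. Peak lists of the 2 ChIP replicates and 1 series-level list were analysed, with scores as given by the authors' peak caller, and the depth behind them is unknown.

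Replicate 1 had 1579 peaks and replicate 2 had 4403, a mean of 2991 ± 1997 (SD, n = 2). The fewer peaks of replicate 1 were wider, with a median of 1448 bp against 376 bp in replicate 2. Covered sequence differed in the other direction, at 3.14 Mb (3.13% of the chromosomes) in replicate 1 and 2.36 Mb (2.35%) in replicate 2. The series-level list held 6862 peaks on the 6 nuclear chromosomes, with a median width of 282 bp and a covered length of 2.95 Mb, and 2 peaks on mitochondrial DNA. With 2 lists and no counts, the difference in peak number between replicates could not be tested against replicate error.

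Most peaks of the shorter list were found again in the longer one. Of the 1579 replicate 1 peaks, 1255 (79.5%) overlapped a replicate 2 peak, where random placement gave 157 ± 11.8 (SD over 1000 placements, highest 196). The observed count was 7.99 times that mean (one-sided permutation p = 0.001, the smallest possible). In the other direction 1738 of 4403 replicate 2 peaks (39.5%) overlapped a replicate 1 peak, 9.05 times the 192 expected by placement (one-sided permutation p = 0.001). 318 replicate 1 peaks lay over 2 or more replicate 2 peaks. The strongest peaks found without a partner were III:1954456-1959588 in replicate 1 (5133 bp, score 1699) and, tied at the score 3100, II:14601071-14606757 (5687 bp) and X:12663530-12667536 (4007 bp) in replicate 2.

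High-scoring peaks were shared more often than low-scoring ones in both lists. With each list split into 5 equal groups by score, 64.1% of the 315 lowest replicate 1 peaks overlapped replicate 2 (95% interval 58.6 to 69.4), and 93.7% of the 316 highest (90.4 to 96.1). In replicate 2 the share went from 21.6% of 880 peaks (18.9 to 24.5) to 77.8% of 881 (74.9 to 80.5). Random placement was not made for each group. Wider peaks overlap more easily by 1 bp, so the part of peak width in this trend was not tested. Over the 1738 shared peaks the scores of the replicates were correlated across peaks, with a Spearman rho of 0.31 (permutation p = 1e-05, the smallest possible; peaks are not independent replicates). The correlation was 0.74 over the 178 shared peaks on X and 0.25 over the 1560 on autosomes, each with adjusted permutation p = 1e-05 over the 3 correlations. The difference of 0.49 was larger than in any of 2000 permutations of the chromosome label (two-sided p = 5.00e-04, the smallest possible). A replicate 1 peak over several replicate 2 peaks enters more than once, and the permutation treats all pairs as independent, so this p can be too small.

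**Figure D1:**
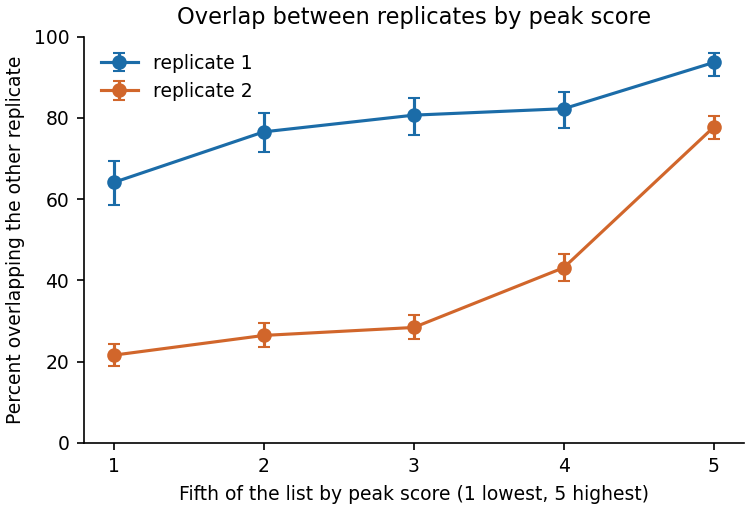
Share of peaks of each replicate that overlap the other replicate by at least 1 bp (y axis, percent) in 5 equal groups by peak score (x axis, 1 lowest to 5 highest). Points are shares and bars 95% exact binomial intervals; the share goes from 64.1% to 93.7% in replicate 1 and from 21.6% to 77.8% in replicate 2.

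The series-level list was neither the union nor the intersection of the replicate lists. It contained an overlapping peak for 97.6% of replicate 1 and 92.9% of replicate 2 peaks (one-sided permutation p = 0.001 for each). None of its peaks had the exact interval of a replicate peak (0 of 6862). 1593 of its peaks (23.2%) overlapped both replicates and had a median score of 26.2. 2440 overlapped replicate 2 only, with a median score of 9.63, 991 overlapped replicate 1 only, with a median of 5.58, and 1838 (26.8%) overlapped neither, with a median of 4.48. Chromosome III held 416 of the 991 peaks that overlapped replicate 1 only (42%) and 516 of the 2440 that overlapped replicate 2 only (21.1%; Fisher's exact test, odds ratio 2.70, whose p is not given because these peaks are clustered). The replicate lists themselves held 22.6% and 21.1% of their peaks on III, a difference that did not pass (Fisher's exact test, odds ratio 1.09, adjusted p = 0.317).

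By number over the whole lists, peaks were densest on chromosome III and sparsest on X. Relative to its length, III had 1.59 ± 0.08 times its share of peaks (mean of replicates, SD, n = 2) and X had 0.52 ± 0.09 times its share. Chromosome V was also below its share, at 0.73 ± 0.03, and chromosome I above it, at 1.28 ± 0.08. Among the shared peaks, 379 of 1738 (21.8%, 95% interval 19.9 to 23.8) lay on III, which makes up 13.7% of the length, and 178 (10.2%, 8.86 to 11.8) lay on X, which makes up 17.7%. In the shared list the ratios were 1.59 for III (exact binomial adjusted p = 2.22e-19), 0.58 for X (1.32e-17), 0.74 for V (9.71e-09), 1.18 for IV (0.00107), 1.11 for I (0.0741) and 1.01 for II (0.868). With windows of 100 kb permuted, III, X and V stayed below an adjusted p of 0.05 in the shared list (2.67e-05, 6.55e-05 and 0.00297) and IV did not (0.0732). By covered bases in place of peak numbers, the V and IV ratios of the shared list did not pass (0.848, adjusted p = 0.151, and 1.14, adjusted p = 0.252), and in the upper 50% of replicate 1 by score the ratio of I was 1.03 (exact binomial adjusted p = 0.793). The III and X ratios lay on the same side of 1 in both replicates and in the series-level list (1.75 and 0.47). In the upper 50% of the shared list by its replicate 2 scores, III (1.25) was close to I (1.26) and IV (1.24). In the upper 50% of the other lists III had the highest ratio. It was 1.68 in replicate 1 (next IV, 1.15), 1.45 in replicate 2 (next I, 1.41) and 1.65 in the series-level list (next I, 1.35). Between 1.0 and 2.5 Mb lay 130 of 357 III peaks in replicate 1 and 116 of 928 in replicate 2. In the shared list 102 of 379 III peaks lay there. That region was picked after the values were seen, and the III ratio without it was not computed. By peak number, X held a larger share of replicate 1 (10.3%) than of replicate 2 (7.95%; Fisher's exact test, adjusted p = 0.0327), and II a smaller one (13.5% and 16.1%; adjusted p = 0.0442). The X ratios by covered bases hardly differed, at 0.589 in replicate 1 and 0.583 in replicate 2, and those of II were 0.835 and 0.969. Fisher's exact test counts neighbouring peaks as independent, and no window test of these replicate differences was made.

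**Figure D2:**
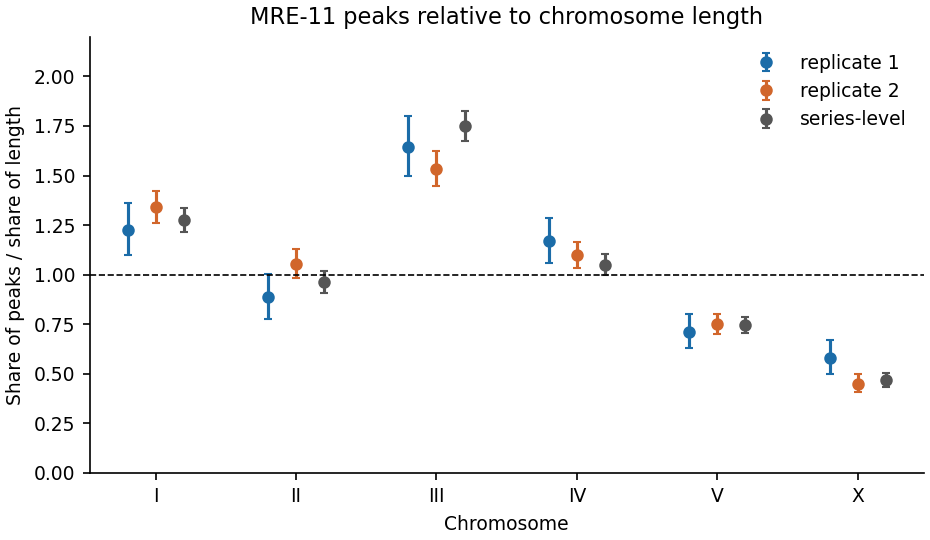
Share of peaks on each chromosome divided by its share of the summed chromosome length (y axis) for the 6 nuclear chromosomes (x axis) in replicate 1, replicate 2 and the series-level list. Bars are 95% exact binomial intervals and the dashed line is the value for peaks spread by length; III lies at 1.53 to 1.75 and X at 0.45 to 0.58.

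The replicates differed in where along the autosomes their peaks lay. In replicate 1, 1082 of 1417 autosomal peaks (76.4%, 95% interval 74.1 to 78.5) had their midpoint on the arms, the end segments that make up 66.7% of each chromosome, above that share of the length (exact binomial adjusted p = 1.51e-14). In replicate 2 the share was 66.1% of 4053 (64.6 to 67.5; exact binomial adjusted p = 0.424). The difference of 10.3 percentage points had p = 2.80e-13 by Fisher's exact test and p = 1e-05 when 100 kb windows were permuted. The shared peaks lay there in 74.2% of cases (exact binomial adjusted p = 6.01e-10). When each list was tested against length by permuted windows, the adjusted p was 8.0e-05 for replicate 1, 0.663 for replicate 2 and 0.00128 for the shared peaks. Of the autosomal peaks without a partner, 89.1% of 294 in replicate 1 and 61.0% of 2493 in replicate 2 lay on the arms. On X the share was above expectation in both replicates, at 80.9% of 162 peaks (exact binomial adjusted p = 1.06e-04) and 78.6% of 350 (exact binomial adjusted p = 2.01e-06). Permuted windows gave an adjusted p of 0.0172 for X in each replicate. The replicates were not distinguishable on X (difference 2.29 percentage points, Fisher's exact adjusted p = 0.639).

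**Figure D3:**
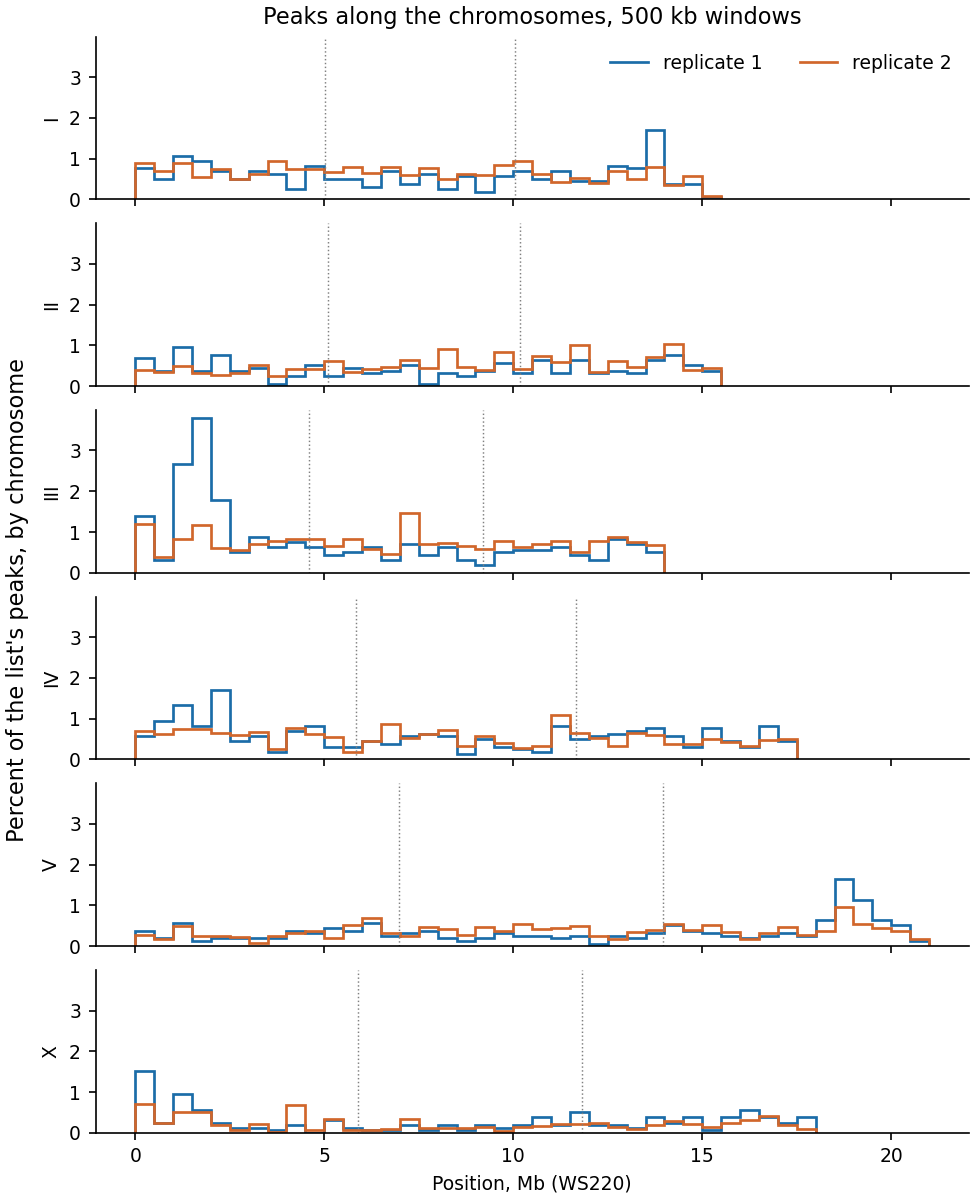
Percent of each replicate's peaks (y axis, 1 panel per chromosome) by midpoint position in Mb on WS220 (x axis) in 500 kb windows. Dotted lines mark the inner ends of the arms; the highest window of replicate 1 is III:1500001-2000000 with 60 peaks, and that of replicate 2 is III:7000001-7500000 with 65.

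X held few peaks but a large share of the highest-scoring ones. In the series-level list the 27 highest scores were all on X, from 219.89 down to 177.57, and the highest autosomal peak, III:1618674-1619339, followed with 172.07. The 20 highest lay between X:409882 and X:17544765, a median of 854 kb apart, and had a median width of 1014 bp, against 621 bp for the 20 highest autosomal peaks of the same list. Those with the highest scores were X:806405-806984, X:1626614-1627698 and X:16055875-16057111, each at 219.89. Of the 100 highest series-level peaks 37 were on X, against 529 of the other 6762 (7.82%; Fisher's exact test, odds ratio 6.92, adjusted p = 2.24e-15). Of the 200 highest 43 were on X (21.5%, odds ratio 3.21, Fisher's exact adjusted p = 2.78e-09), so only 6 lay in the second 100, and the excess on X was held by the top of the list. In replicate 1, 32 of the 100 highest were on X against 8.79% of the rest (Fisher's exact test, odds ratio 4.88, adjusted p = 5.40e-10), and in replicate 2, 31 of 100 against 7.41% (odds ratio 5.61, adjusted p = 1.53e-11). Among the 200 highest the share on X was 27% in replicate 1 and 23% in replicate 2. The comparison by score rank was chosen after the values were seen.

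**Figure D4:**
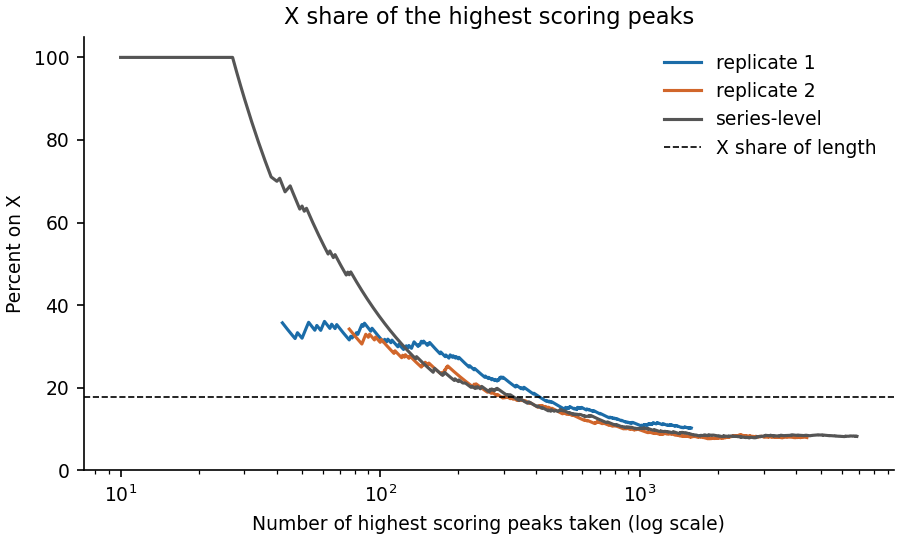
Percent of peaks on X (y axis) among the highest-scoring peaks of each list, by the number of peaks taken (x axis, log scale); tied scores enter together. The dashed line is the X share of chromosome length, 17.7%; in the series-level list X holds 37 of the top 100 peaks and 8.25% of all.

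The 35 named shared peaks differed in replicate 2 width between X and the autosomes, in the opposite direction to the widths of the 20 highest series-level peaks. 13 were on X, 7 on I, 5 on III, 4 on IV, 4 on V and 2 on II. 9 of the X peaks were narrower than 1500 bp in replicate 2, among them X:2996261-2997538 (1278 bp), X:8035899-8036967 (1069 bp), X:9465430-9466218 (789 bp) and X:14525251-14526442 (1192 bp), whose series-level scores were 218.57, 217.61, 216.33 and 218.57. The other 4, X:109432-114278, X:289745-295384, X:2057797-2063924 and X:15807426-15811279, were 3854 to 6128 bp wide with series-level scores of 70.81 to 79.49. The autosomal peaks were mostly broad. The widest was I:15060286-15071351 (11066 bp), near the right end of chromosome I, where the ribosomal RNA gene array of the worm lies. It was followed by V:7916696-7925076 (8381 bp), III:6566760-6574506 (7747 bp) and I:10945911-10953090 (7180 bp). The median width was 1192 bp on X and 3694 bp on autosomes (two-sided permutation test of ranks, adjusted p = 0.0133), and the median series-level score was 204.71 on X and 75.74 on autosomes. A test of those scores adds nothing, since the X peaks narrower than 1500 bp are among the 20 highest of the series-level list. Their replicate scores, at 3100 to 3199, could not rank these peaks against each other.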

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

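The series-level list held 2 peaks on mitochondrial DNA, a signal outside the chromosomes compared above, at positions 1 to 10549 (score 45.94) and 10748 to 13304 (score 30.58), while neither replicate list held any.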

How the results depend on the processing

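The permuted windows, the arms without chromosome III, the scores capped at 3100 or apart by chromosome class, and the X share of the top peaks with its alternatives were chosen after seeing the data. Of 138 alternative values for 48 results, 120 were counted as unchanged, among them every alternative for III, X, the overlap of the replicates, the score correlation and the X share of the top peaks. For tested results this meant the same side of the threshold, and the same direction only where the main value passed. The ratio of II, which did not pass, crossed 1 by covered bases in replicate 2 (0.969) and the shared list (0.923), and in the upper 50% of the shared list (0.974). Values without a p-value were judged by how far they moved. Leaving out 1 replicate could change the label of a mean ratio only if it crossed 1. The X ratio of the shared list ranged from 0.58 to 0.71, its III ratio from 1.25 to 1.59, and the fold of overlap over placement from 6.06 to 10.9. No alternative for the III ratio left out the dense left part of III. The mean peak number was 1495 in the upper 50% by score, where the cut itself sets it, and 1579 to 4403 with 1 replicate. The causes of the changes below were not tested. In the upper 50%, the ratios of I and IV in replicate 1 lost their calls (1.03 and 1.15), II in replicate 1 (0.757) and I in the shared list (1.26) gained one, and the arm ratio of autosomes in the series-level list lost it (1.01). By covered bases, tested by permuted windows in place of the binomial test, calls were lost for I, IV and V in replicate 1 (1.05, 1.06 and 0.804). They were also lost for IV in replicate 2 (1.07), and for IV and V in the shared list (1.14 and 0.848). With permuted windows and peak numbers kept, IV lost its call in replicate 1 (1.17), replicate 2 (1.10) and the shared list (1.18). The losses of IV by covered bases can therefore not be put down to the measure alone. With 1 replicate left out, the mean ratio of II ranged from 0.885 to 1.05 and the mean arm ratio of autosomes from 0.991 to 1.15, both crossing 1: without replicate 1 no arm excess on autosomes remained. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no peak list analysed here. Alternatives for genomic features and gene lists were not run. Read depth, which limits how many peaks a list can hold, is unknown for both replicates.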

Other observations

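Of the tests below, those on the scoring of the series-level list, on the length of the replicate 2 list and on the chromosome starts were chosen after the result was seen. The tests of the arm difference between replicates address a comparison that was itself chosen after seeing the data. The one without chromosome III addresses a region that was picked after the values were seen. MRE-11 peaks lay at the left end of every chromosome. The first peak of all 6 chromosomes started at base 1 or 2 in each of the 3 lists. In replicate 2 these peaks were 218 to 520 bp wide with scores of 249 (III) to 1118 (I), and in replicate 1 they were 645 to 2355 bp wide with scores of 59.5 (IV) to 728 (I). 0 of 1000 random placements of the replicate 2 peaks put a peak in the first 1000 bp of all 6 chromosomes, and the highest number reached was 2, so random position does not account for them. Worm chromosomes end in telomere repeats, and reads from repeats elsewhere could pile up at such ends; with base 1 covered on 6 of 6 chromosomes and no mapping quality in the lists, that stays open, as does MRE-11 at telomeres. The right ends had no such test, because chromosome lengths were taken from the peaks themselves. The last peak of each replicate ended at a lower position than the last series-level peak on every chromosome, although on I that of replicate 1 overlapped it: on V, replicate 1 ended at 20846208, replicate 2 at 20852341 and the series-level list at 20924172, and on IV they ended at 17281742, 17493000 and 17493816.

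The left part of chromosome III was dense in all 3 lists. Between 1.0 and 2.5 Mb on III, a region picked after the values were seen, replicate 1 had 130 peaks, 5.50 times the share of its length, and replicate 2 had 116, 1.76 times, and the series-level list had 447, 4.35 times; Fisher's exact test of the replicates there gave an odds ratio of 3.32, which is no independent evidence of a difference, because the region was picked as the densest of replicate 1. Its 3 windows of 500 kb were the densest of replicate 1 and of the series-level list, and III:1500001-2000000, with 52 peaks, ranked 3 in replicate 2. The median 500 kb window held 6 peaks in replicate 1 and 21 in replicate 2.

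The 20 highest series-level peaks, all on X, may be sites of an X-specific machinery. All 20 of the highest series-level peaks overlapped peaks of both replicates (20 of 20), which argues against signal from 1 replicate, and the lower of the replicates' odds ratios for X among the top 100 was 4.88 (Fisher's exact p = 4.63e-10), which argues against the scoring of the series-level list as the whole cause. Multi-copy DNA stays open: the median width of 1014 bp does not decide, since repeats can be of any length. The comparison laid down for multi-copy DNA, once the pattern on X was known, was with autosomal peaks of top score in both replicates. The named peaks had replicate 2 medians of 1192 bp on X and 3694 bp on autosomes, while the 20 highest autosomal series-level peaks had a median of 621 bp. No biological explanation was tested. A hypothesis that lists of known sites could test is that these are recruitment sites of the dosage compensation complex, which binds the X chromosomes of hermaphrodites, and another is that they are sites enriched with any antibody; neither such sites nor other antibodies were analysed here.

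Replicate 1 lay on autosome arms more often than replicate 2 (76.4% and 66.1%), and 3 explanations were tested. Weaker peaks in the longer list would be removed by taking the highest-scoring replicate 2 peaks, as many as replicate 1 has, but these lay on arms in 64.3% (Fisher's exact p = 1.87e-12 against replicate 1). Merging by wider calls was imitated by widening replicate 2 peaks to 1448 bp and joining them. This left 3452 peaks with 65.2% on arms (Fisher's exact p = 3.10e-14 against replicate 1). That is more than the 1579 peaks of replicate 1, so stronger merging than was imitated stays open. Without chromosome III the difference was 9.27 percentage points (75% and 65.7%, Fisher's exact p = 1.59e-08), so the dense region there is not the whole cause. A difference between the libraries, their inputs, the peak calling settings or the animals cannot be separated with 1 library per replicate and was not tested.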
